A study of Rattus norvegicus and Homo sapiens with 570 samples.

How the data were processed

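Total RNA of rat primary hepatocytes and of human HepaRG cells was measured by RNA sequencing after exposure to DMSO, to the compounds labelled 3MC and PHB, or to 15 further compounds per cell type at 5 doses each. The labels state that RNA was isolated with a MagMax mirVana kit on a KingFisher Flex and had a quality score of at least 7. Group, dose, batch and replicate number of each library were taken from the sample titles. The labels name 286 rat and 284 HepaRG samples, of which 284 and 278 had a column of values. Without a column were rat Amit 10 replicate 1 and Sulf 0.1 replicate 2, and in HepaRG Mef 3 replicate 1, Ethio 0.1 replicate 3, Tri 3 replicate 3, Tri 0.3 replicate 2 and DMSO replicates 1 and 2 of batch 3. Doses carry no unit in the labels and are printed as given, and compound abbreviations were not expanded.

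The deposited gene tables hold raw counts per Ensembl gene ID, as whole numbers without normalization, for 32852 rat and 66902 human IDs. Per the submitters' processing notes, Salmon 1.2.0 and DESeq2 were used with the builds mRatBN7.2 and GRCh38.p13. The deposited counts may thus be rounded estimates in which reads shared by similar genes were divided between them. A further pair of tables holds variance-stabilised values of the authors on a log2-like scale. In these, a step of 1 in log2 counts moved the value by 0.96 in rat and 0.91 in HepaRG at high counts, but by 0.32 and 0.26 at low counts. The 92 ERCC spike-in controls of each table were left out of every fit. They made up 0.297 to 2.461% of the counts of rat libraries and 0.435 to 3.862% of HepaRG libraries.

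Human IDs were joined to symbols through the name table for 60346 IDs, and coordinates are those of GENCODE release 29 on GRCh38. No table joining rat IDs to symbols was used here. Rat results are therefore counts of genes and a few IDs, and the gene lists and the planned comparison of the 13 identical labels between rat and HepaRG could not be run.

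Each compound was fitted with its 5 doses and the DMSO libraries of its own batch in edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM factors and the quasi-likelihood F test, and each dose was compared with DMSO. For 3MC and PHB, all 3 batches were fitted together with batch as a term. BLANK, labelled in rat only, was fitted with DMSO in the same way. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. Between 11902 and 12986 rat genes and between 17602 and 19498 human genes were tested per fit. The lowest active dose of a compound was the lowest one at which it and every higher dose changed at least 20 genes. Folds and log2 fold changes come from the fit. They are followed by an approximate standard error, worked back as the log2 fold change over the square root of its F statistic. It may be too small for genes with few counts in a group. Levels in CPM are on library sizes scaled by the TMM factors and are means with the SD between libraries.

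Human gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over all 424 pairs of list and comparison, and repeated with the correlation estimated from the data. Lists of at least 3 measured members were tested. The 25 lists were AhR targets, CAR and PXR targets, PPARA targets, bile acid synthesis and transport, cholesterol synthesis and uptake, fatty acid synthesis, the unfolded protein response of the endoplasmic reticulum, the integrated stress response, NRF2 targets, p53 targets, cytosolic heat shock proteins, metallothioneins, tubulins, cell division, hepatocyte secreted proteins and enzymes, acute phase proteins, gluconeogenesis and glucocorticoid response, retinoic acid response, conjugation of thyroid hormone and steroids, mitochondrially encoded proteins, glycolysis and hypoxia response, and markers of cholangiocytes and progenitors, stellate cells and fibroblasts, macrophages and leukocytes, and endothelium. Numbers of list members that rose or fell are over all genes tested. Adjusted over the list alone, they differed in 4 of the 424 pairs, by 1 gene each.

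Lists, tests, thresholds and the rule for named genes were fixed before the data were examined. For a highest dose with at least 20 changed genes, the rule took the 3 largest rises and 3 largest falls (10 each for 3MC and PHB) among genes with a symbol, at least 5 CPM in the higher group and no overlap between treated and DMSO libraries. It added up to 6 changed members of each called list, and up to 3 genes where fewer than 20 changed. CYP1A1, CYP1A2, CYP2B6 and CYP3A4 were always named for 3MC and PHB. A fold against a group without any count is a lower bound computed against 3 counts over the group, which covers counting error only. Genes with 1 to 3 counts in a group are given as levels.

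On simulated data with the depth and spread of these libraries, in which 50 genes changed at each of 4 folds, the fit of 4 treated and 7 HepaRG DMSO libraries called 0% of the 1.5-fold changes, 80% of the 2.5-fold and 96% of the 4-fold and 8-fold changes, with 3 unchanged genes called. In the design of 12 and 19 HepaRG libraries these shares were 2%, 96%, 94% and 98%, with 0 unchanged genes called by edgeR. A 1.5-fold change is smaller than a call requires, so its low share is set by the threshold and does not measure power. In rat, 82% of 2.5-fold changes were called with 3 treated and 7 DMSO libraries. Of 20 random lists, camera called 0 at an unadjusted p under 0.05 in either HepaRG design. The simulated genes were drawn independently of each other, so this cannot show how camera behaves on lists of correlated genes.

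Whether replicate numbers paired the libraries is not settled. The median correlation between libraries of the same number in different groups of a batch lay between -0.001 and 0.04. For different numbers it lay between -0.019 and -0.002. Of the same-number pairs, 16.4% (HepaRG batch 2) to 42.3% (rat batch 1) exceeded 0.1. On average, 59 of 90 libraries in rat batch 1 and 47 of 84 in HepaRG batch 3 correlated more with their own number than with others. Replicate numbers were used as a block only as an alternative, so the main fits leave a possible pairing out of account. No 2 replicates of a group differed by as little as repeated sequencing of 1 library would, since the chi-square per gene was at least 2.46. Alternatives were DESeq2 size factors, no filter on low counts, each replicate number left out in turn and a replicate block. A replicate number of a compound was left out at all its doses. In the fits of 3MC, PHB and BLANK a number was left out in every batch, but BLANK libraries 1 at a time. The DESeq2 1.42.0 Wald test, limma on the variance-stabilised values, 1 fit over all groups of a batch and each batch alone were further alternatives. So were a minimum of 5 or 100 changed genes for an active dose, and the estimated correlation for lists. Every count was ranked among 25 splits of the same libraries, the real one included. Shares of mitochondrial and spike-in counts were compared by exact permutation tests, two-sided. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.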

Results

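Expression was measured in rat primary hepatocytes and in the human hepatic cell line HepaRG after exposure to 15 compounds per cell type, each at 5 doses, beside DMSO and the compounds labelled 3MC and PHB. The data held 284 rat and 278 HepaRG libraries. Each compound was run in 1 of 3 batches with 7 DMSO libraries (5 in HepaRG batch 3), in most cases with 3 libraries per dose and 4 at the highest dose. 3MC and PHB had 4 libraries in every batch. Counts assigned to genes ran from 5063241 to 15438673 per rat library (median 10829883) and from 8077923 to 102060676 per HepaRG library (median 15343109). Doses have no unit in the labels, so no dose is compared between compounds or cell types. All p-values measure the spread between libraries alone, and the labels do not say whether replicates came from separate cultures, so that part of this spread may be technical. The question addressed was which genes and pathways each compound changed, and from which dose.

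3MC raised the cytochrome P450 genes of the CYP1 family in HepaRG, the classical targets of the aryl hydrocarbon receptor (AhR). CYP1A2 rose 14.9-fold (log2 3.90 ± 0.08, 110.9 ± 20.8 against 7.53 ± 1.4 CPM in DMSO, adjusted p = 8.17e-27), CYP1B1 11.2-fold (log2 3.49 ± 0.05) and CYP1A1 9.79-fold (log2 3.29 ± 0.10, adjusted p = 1.64e-22), in 12 treated against 19 DMSO libraries. ALDH3A1, an aldehyde dehydrogenase, rose 6.01-fold (2.59 ± 0.07) and TIPARP, which represses AhR, 2.27-fold (1.18 ± 0.06). The largest rise was that of SERPINB2, an inhibitor of plasminogen activators, at 23.2-fold (4.54 ± 0.06, 64.4 ± 11 against 2.74 ± 0.625 CPM), followed after CYP1A2 by the tachykinin precursor TAC1 (3.53 ± 0.15). Falls were smaller: ACSS1 (-1.94 ± 0.10), an acetyl-CoA synthetase of mitochondria, THRSP (-1.77 ± 0.11), a promoter of lipid synthesis, PCK1 (-1.59 ± 0.12) and G6PC1 (-1.35 ± 0.08), which catalyse steps of gluconeogenesis, CYP7A1 (-1.39 ± 0.11), the rate-limiting enzyme of bile acid synthesis, and CYP3A4 (-1.24 ± 0.05, 560.0 ± 94.1 against 1329 ± 126 CPM). CYP2B6 was at 0.17 ± 0.09 (adjusted p = 0.148).

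Of 8 AhR targets, 5 rose with 3MC (median log2 fold change 1.89, adjusted p = 2.26e-13, and 0.000493 with an estimated correlation), and the same number passed when adjusted over the list alone. Cholesterol synthesis and uptake was lower as a group although 0 of its 25 members were called by edgeR (median -0.36, adjusted p = 5.08e-19, and 0.0378 with an estimated correlation). NRF2 targets were higher (median 0.23, adjusted p = 6.31e-08, and 0.0055 with an estimated correlation), and gluconeogenesis and glucocorticoid response was lower, with 2 of 9 members called (0.00421 and 0.0331). CAR and PXR targets were called lower with the preset correlation (median -0.39, adjusted p = 3.17e-05), but not with an estimated correlation (adjusted p = 0.131). In total 84 genes rose and 87 fell, and the batches alone gave 185, 240 and 208 changed genes. The total was 749 without a filter on low counts and 22 with limma on the variance-stabilised values, which did not call ACSS1 (-0.90), THRSP (-0.94) or PCK1 (-0.76).

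PHB raised the genes of the other classical group of drug metabolism, that of the receptors CAR and PXR. In HepaRG, CYP3A4, the main drug-oxidising enzyme of the liver, rose 5.53-fold (2.47 ± 0.04, 7161 ± 598 against 1305 ± 123 CPM, adjusted p = 3.21e-29), and CYP2B6 rose 4.86-fold (2.28 ± 0.10, 740.6 ± 141 against 152.9 ± 28.7 CPM, adjusted p = 7.88e-18), in 12 treated against 19 DMSO libraries. CYP2C19 (1.31 ± 0.07), CYP2A6 (1.27 ± 0.10) and CYP2C8 (1.26 ± 0.04) also rose, as did ALAS1 (1.09 ± 0.05), the first enzyme of heme synthesis, and AKR1D1 (1.14 ± 0.09), a steroid reductase of bile acid synthesis. MYH4, a myosin heavy chain, was the largest rise (3.68 ± 0.20) from a low level of 0.458 ± 0.25 CPM. CYP1A1 was at 0.06 ± 0.11 (adjusted p = 0.82) and CYP1A2 at -0.28 ± 0.09 (adjusted p = 0.0717).

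Of 13 CAR and PXR targets, 6 rose with PHB (median 0.98, adjusted p = 1.54e-70, and 9.25e-08 with an estimated correlation). Conjugation of thyroid hormone and steroids was higher as a group (median 0.42, adjusted p = 2.59e-16, and 0.00346 with an estimated correlation), with 0 of 12 members called by edgeR. Altogether 23 genes rose and 8 fell, and each batch alone gave 20, 18 and 19. The total was 68 without the low-count filter and 8 with limma on the variance-stabilised values, which did not call AKR1D1 (0.94) or ALAS1 (1.00). AKR1D1 was not called in batch 3 alone either. CYP2B6 has a near-identical pseudogene, CYP2B7P (1.73 ± 0.09), and the CYP3A and CYP2A genes have close relatives, so the division of reads within these families is uncertain here and below. CYP1A1 lies on chromosome 15 at 74719542 to 74725610 (reverse strand), CYP1A2 on the same chromosome at 74748844 to 74756202 (forward), CYP2B6 on chromosome 19 at 40991250 to 41018398 (forward) and CYP3A4 on chromosome 7 at 99756960 to 99784265 (reverse), all on GRCh38.

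**Figure D1:**
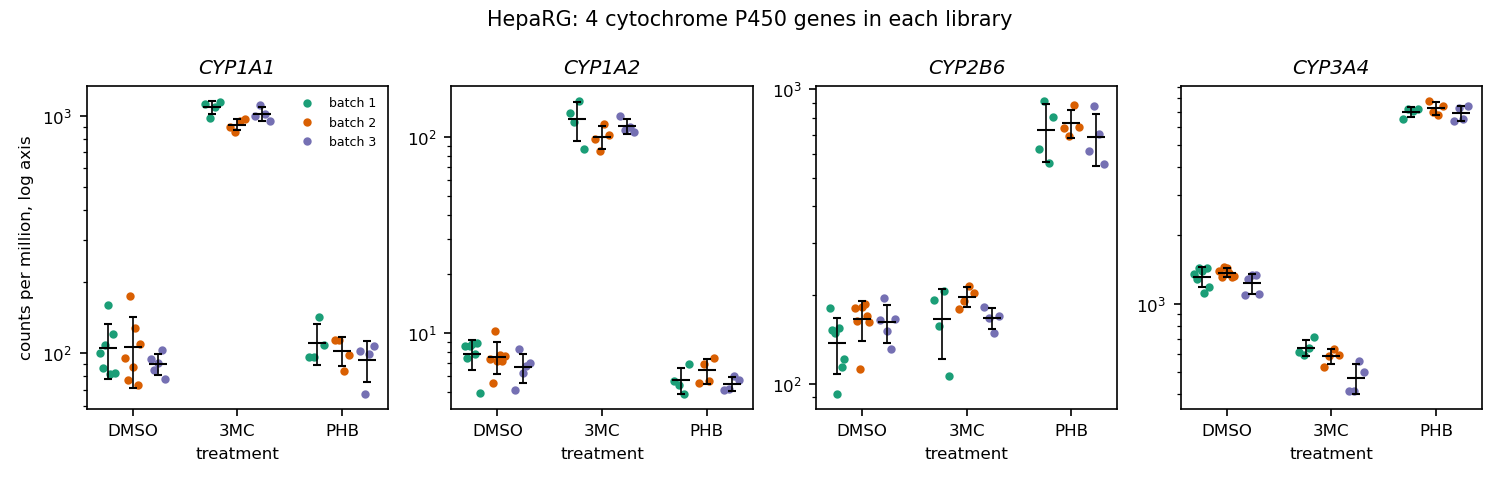
Level of CYP1A1, CYP1A2, CYP2B6 and CYP3A4 in CPM (log axis) in each HepaRG library of DMSO, 3MC and PHB, coloured by batch, with bars for the mean and SD of each batch. CPM are on total gene counts without TMM factors, so they differ slightly from the levels in the text. CYP1A1 lay between 856 and 1142 with 3MC against 73.6 to 174 in DMSO, and CYP3A4 between 6355 and 7817 with PHB against 1093 to 1457 in DMSO.

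Some of the genes that PHB raised, CYP2B6 and CYP3A4 foremost, also rose with other compounds in HepaRG. Phe at 30 changed 6 genes, among them CYP2B6 (2.16 ± 0.10, 738.3 ± 48.2 against 164.5 ± 26.1 CPM), CYP3A4 (1.27 ± 0.06) and CYP2A6 (1.16 ± 0.12), in 4 treated against 7 DMSO libraries. CYP2B6 was raised by Phe at dose 3 (467.0 ± 52.4 CPM), 10 (1.86 ± 0.11) and 30. Pro at 100 raised CYP3A4 5.43-fold (2.44 ± 0.08, 6642 ± 153 against 1223 ± 125 CPM) and CYP2B6 3.89-fold (1.96 ± 0.11), with ALAS1 (1.29 ± 0.08) and CYP2C8 (1.07 ± 0.19), in 4 against 5 DMSO libraries. CYP3A4 had risen from dose 10 of Pro (1.49 ± 0.08). Pro lowered CYP2E1 (-2.51 ± 0.24), which oxidises ethanol and other small molecules, CYP7A1 (-1.50 ± 0.21) and the tyrosine aminotransferase TAT (-1.67 ± 0.20). Of the CAR and PXR targets, 3 of 13 rose with Phe (adjusted p = 2.07e-47, and 2.06e-05 with an estimated correlation) and 4 of 13 with Pro (1.28e-17 and 0.00543). NRF2 targets were higher with Pro as a group (median 0.39, adjusted p = 2.02e-17, and 0.00325 with an estimated correlation). Of the cell type markers, 1 of 6 for cholangiocytes and progenitors rose and 1 of 5 for endothelium fell with Pro, without a call for either list. Pro changed 201 genes, 78 of them upward, and 40 with limma on the variance-stabilised values or 104 with a replicate block.

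Tri and Sul raised members of both groups in HepaRG. Tri at 300 raised CYP1A2 5.70-fold (2.51 ± 0.15, 37.92 ± 6.67 against 6.67 ± 1.17 CPM), CYP1A1 4.27-fold (2.09 ± 0.08), CYP2B6 3.15-fold (1.65 ± 0.11) and CYP3A4 2.06-fold (1.04 ± 0.08), in 4 against 5 DMSO libraries. It lowered the lysolipid transporter MFSD2A (-2.23 ± 0.09), the bile salt export pump ABCB11 (-1.71 ± 0.16) and G6PC1 (-1.66 ± 0.20). Sul at 300 changed 4 genes, among them CYP3A4 (1.23 ± 0.09), CYP1A2 (1.15 ± 0.14) and CYP2B6 (1.12 ± 0.12), in 4 against 5 libraries. AhR targets were higher as a group with Tri (2 of 8 members called, adjusted p = 2.82e-08, and 0.00227 with an estimated correlation) and Sul (1 of 8, 1.12e-08 and 0.00128). CAR and PXR targets were higher with Tri (2 of 13, 3.03e-21 and 0.0106) and Sul (2 of 13, 6.82e-38 and 0.000493). Tri changed 59 genes, but 34 without replicate 2, 35 without DMSO replicate 5, 30 with a replicate block and 8 with limma on the variance-stabilised values. Sul changed 9 genes with DESeq2 and 2 with that limma fit, which did not call CYP1A2 (0.72).

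Buc at 300 changed CYP2B6 (1.08 ± 0.17, 288.1 ± 57.4 against 136.6 ± 30.6 CPM, adjusted p = 0.0165) and CYP2A7 (1.02 ± 0.17) in HepaRG, in 4 against 7 libraries. CAR and PXR targets were higher as a group (median 0.25, adjusted p = 3.23e-18, and 0.00325 with an estimated correlation). Neither gene was called without treated replicate 2, 3 or 4 (CYP2B6 0.95, 1.09 and 1.06), without DMSO replicate 4 or 6 (1.00 and 1.04) or with a replicate block (1.05), each of which gave 0 genes in edgeR. CYP2A7 was not called without DMSO replicate 7 either (0.98). At an unadjusted p under 0.05, 1443 genes differed, and DESeq2 and limma on the variance-stabilised values called 1 each. Fen at 30 raised CYP2B6 (1.16 ± 0.18) and STC2 (2.46-fold, 6.12 ± 1.2 against 2.48 ± 0.14 CPM), a secreted glycoprotein, and lowered the acute phase protein CRP (-1.29 ± 0.28) and the helicase PIF1 (-1.17 ± 0.12), in 4 against 5 libraries. CRP was not called without treated replicate 2 (-1.13). The acute phase proteins were lower as a group (median -0.42, adjusted p = 9.23e-22, and 0.0273 with an estimated correlation), with 1 of 15 members called. Fen changed 30 genes, but 18 without replicate 1, 7 with a replicate block, which did not call STC2 (1.34), CYP2B6 (1.00) or CRP (-1.28) although the folds were similar, and 6 with limma on the variance-stabilised values, which did not call STC2 (0.59) or PIF1 (-0.69).

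Ket raised the genes of cholesterol synthesis in HepaRG. At 100, INSIG1, which restrains the activation of sterol synthesis, rose 7.53-fold (2.91 ± 0.08, 2426 ± 117 against 322.3 ± 45.4 CPM) and HMGCS1, which acts early in the pathway, 4.50-fold (2.17 ± 0.06), in 4 against 7 libraries. ACLY, which makes cytosolic acetyl-CoA, rose 4.46-fold (2.16 ± 0.04) and the fatty acid synthase FASN 2.68-fold (1.42 ± 0.07). Genes of the integrated stress response rose too, with CHAC1, which degrades glutathione, at 3.07 ± 0.19, TRIB3, a pseudokinase induced by ATF4, at 2.88 ± 0.08 and the asparagine synthetase ASNS at 2.53 ± 0.10. Genes induced by hypoxia fell, such as the carbonic anhydrase CA9 (-3.70 ± 0.22), EGLN3 (-2.95 ± 0.19) and NDRG1 (-2.87 ± 0.19), as did the proliferation marker MKI67 (-2.53 ± 0.10). The largest rises included the phospholipase gene PLCH2 (5.60 ± 0.17), and the falls IGFBP1 (-3.92 ± 0.37) and ANGPTL4 (-3.91 ± 0.27). KRBA1 was at 0.0329 ± 0.0658 against 5.54 ± 2.29 CPM.

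Of 25 genes of cholesterol synthesis and uptake, 22 rose with Ket (median 1.70, adjusted p = 8.19e-33, and 0.0165 with an estimated correlation). Fatty acid synthesis (5 of 13, 4.38e-08 and 0.0458) and the integrated stress response (11 of 16, 1.08e-12 and 0.0165) were higher, and cell division was lower (14 of 21, median -2.15, 4.18e-20 and 0.0106). Glycolysis and hypoxia response was lower with the preset correlation (9 of 16, median -1.10, adjusted p = 1.73e-07), but adjusted p = 0.265 with an estimated correlation. Of the cell type markers, 2 of 5 for cholangiocytes and progenitors rose (median 0.80) and 1 of 5 for endothelium fell, without a call for either list. INSIG1 was called from dose 10 (2.31 ± 0.09), at 30 (2.85 ± 0.09) and at 100. Ket changed 237 genes at 10, 2001 at 30 and 1216 at 100, of which 463 rose. At the last dose limma on the variance-stabilised values called 349.

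Amit raised cholesterol synthesis as well, in another batch with other DMSO libraries. At 100, INSIG1 rose 3.93-fold (1.97 ± 0.06, 1476 ± 54.2 against 375.9 ± 30.1 CPM), the lanosterol synthase LSS by 1.68 ± 0.05 on the log2 scale and the stearoyl-CoA desaturase SCD 2.69-fold (1.43 ± 0.06), in 4 against 7 libraries. TRIB3 rose 4.61-fold (2.20 ± 0.09), and TAC1 (5.54 ± 0.20) and KCP (6.36 ± 0.37), a modulator of BMP signals, were among the largest rises. KIF20A (-3.62 ± 0.14), a kinesin of cell division, and MKI67 (-3.09 ± 0.13) fell, with CYP4A11 (-2.96 ± 0.15), which hydroxylates fatty acids, and CPS1 (-2.11 ± 0.09), the first enzyme of the urea cycle. Of cholesterol synthesis and uptake, 19 of 25 rose (median 1.34, adjusted p = 1.23e-24, and 0.0109 with an estimated correlation), and of the integrated stress response 7 of 16 (6.79e-08 and 0.0034). Of cell division, 17 of 21 fell (median -2.63, 4.18e-20 and 0.0313). Of the cell type markers, 2 of 5 for endothelium, 2 of 11 for stellate cells and 1 of 5 for cholangiocytes and progenitors fell and 1 for stellate cells rose, without a call for any of these lists. The share of counts from mitochondrial genes was 10.5 ± 0.27% against 12.6 ± 0.547% in DMSO (exact permutation test, adjusted p = 0.03). Amit changed 1512 genes, 553 of them upward, or 421 with limma on the variance-stabilised values.

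Myc at 300 changed 4081 genes in HepaRG, of which 1376 rose and 2705 fell. The largest fitted rise among the named genes with counts in DMSO was that of KCP, at 260.0-fold (8.02 ± 0.30, 70.71 ± 25.6 against 0.263 ± 0.141 CPM). Genes of the integrated stress response rose together: TRIB3 rose 21.2-fold (4.41 ± 0.08, 527.4 ± 61 against 24.86 ± 2.32 CPM), CHAC1 26.7-fold (4.74 ± 0.20) and the transcription factors ATF3 16.6-fold (4.05 ± 0.08) and DDIT3 15.9-fold (3.99 ± 0.08), in 4 against 5 libraries. GDF15, a secreted factor of stressed cells, rose 44.2-fold (5.46 ± 0.10), and the liver hormone FGF21 at least 391-fold, from 0 counts in DMSO. The cystine transporter SLC7A11 (2.78 ± 0.08) and the cell cycle inhibitor CDKN1A (1.08 ± 0.06) rose as well. CYP7A1 fell to 0.165 ± 0.156 from 31.31 ± 8.71 CPM (-7.42 ± 0.39). CYP8B1, also of bile acid synthesis (-5.95 ± 0.12), and CPS1 (-3.68 ± 0.09) fell too. The ribonucleotide reductase subunit RRM2 (-5.43 ± 0.08) and MKI67 (-4.42 ± 0.11) fell with them. SULT1E1, which sulfates estrogens, fell at least 83.4-fold to 0 counts, and PCK1 was at 0.0353 ± 0.0413 against 7.61 ± 0.528 CPM.

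Of the integrated stress response, 14 of 16 rose with Myc (median 2.17, adjusted p = 1.31e-09, and 0.0165 with an estimated correlation), and of p53 targets 6 of 16 (3.57e-05 and 0.0243). In bile acid synthesis and transport 8 of 13 fell and 1 rose (median -1.34, 5.74e-05 and 0.0225). Cell division fell in 19 of 21 members, 20 adjusted over the list alone (median -3.16, adjusted p = 2.26e-13), hepatocyte proteins and enzymes in 11 of 18 (1.26e-05), acute phase proteins in 8 of 15 (8.71e-07) and PPARA targets in 9 of 17, with 1 rise (4.29e-05). For these 4 lists the adjusted p was 0.0574, 0.246, 0.276 and 0.116 with an estimated correlation. Of the mitochondrially encoded proteins, 5 of 13 fell (median -0.86, adjusted p = 1.04e-07, and adjusted p = 0.183 with an estimated correlation), such as MT-CYB (-1.50 ± 0.04). The mitochondrial share of counts was 8.88 ± 0.191% against 12.2 ± 0.532% (exact permutation test, adjusted p = 0.06). Its unadjusted p of 0.016 is the lowest that this test can give for 4 against 5 libraries. Markers of other cell types moved beside these groups without a call for their lists, as 4 of 10 stellate cell markers (median -0.55) and 2 of 3 macrophage markers (median -1.80) fell, and 4 of 6 cholangiocyte and progenitor markers rose while 1 fell (median 1.42). Of the endothelial markers 4 of 5 fell, among them the VEGF receptor KDR (-3.72 ± 0.21), with adjusted p = 0.045 for the list, 0.0591 without replicate 2, 0.0526 without replicate 3 and 0.158 with an estimated correlation. Limma on the variance-stabilised values called 1422 genes.

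Benz at 100 changed 4304 genes in HepaRG, 1880 upward and 2424 downward. ENO2, an enolase of glycolysis, rose 91.6-fold (6.52 ± 0.19, 75.59 ± 14.8 against 0.807 ± 0.264 CPM), the peptide hormone ADM 18.3-fold (4.20 ± 0.19), the angiogenic factor VEGFA 8.79-fold (3.14 ± 0.07), NDRG1 8.02-fold (3.00 ± 0.17) and CA9 5.06-fold (2.34 ± 0.16), in 4 against 7 libraries. ATF3 rose 17.1-fold (4.10 ± 0.10), TRIB3 8.54-fold (3.09 ± 0.08) and the matrix protease MMP10 54.6-fold (5.77 ± 0.32). CYP7A1 fell to 0.433 ± 0.262 from 31.22 ± 7.02 CPM (-6.31 ± 0.30), and MIR122HG, the host transcript of the liver microRNA miR-122, fell too (-6.13 ± 0.16). The vitamin E transfer protein TTPA (-5.17 ± 0.23), the glucuronosyltransferase UGT2B15 (-4.82 ± 0.13), RRM2 (-3.81 ± 0.15) and MKI67 (-3.50 ± 0.15) fell with them, and SULT1E1 fell at least 78.0-fold to 0 counts.

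With Benz, 13 of 16 genes of the integrated stress response rose (median 1.76, adjusted p = 2.04e-07, and 0.00569 with an estimated correlation). Glycolysis and hypoxia response rose in 13 of 16 members (median 1.66, adjusted p = 2.86e-08), cell division fell in 19 of 21 (median -2.52, 2.8e-11) and conjugation of thyroid hormone and steroids in 7 of 12 (median -1.37, 2.28e-06). Tubulins fell in 5 of 10, or 6 adjusted over the list alone (0.000857), and metallothioneins, which bind zinc and copper, rose in 4 of 5 (0.00264). For these 5 lists the adjusted p was 0.227, 0.131, 0.0899, 0.192 and 0.241 with an estimated correlation. Markers of other cell types moved beside these groups without a call for their lists, as 2 of 5 cholangiocyte and progenitor markers rose and 1 fell, 1 of 3 macrophage markers rose and 2 fell, 1 of 5 endothelial markers fell, and 1 of 11 stellate cell markers rose and 1 fell. The mitochondrial share was 10.0 ± 0.392% against 12.6 ± 0.547% in DMSO (exact permutation test, adjusted p = 0.03). Limma on the variance-stabilised values called 1540 genes. At the next lower dose, 31.6, 65 genes changed, with ENO2 at 2.25 ± 0.987 CPM and CYP7A1 at -1.46 ± 0.19.

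Col at 0.1 lowered several genes of bile acid synthesis and gluconeogenesis in HepaRG. CYP7A1 fell to 0.169 ± 0.0662 from 31.92 ± 7.22 CPM (-7.47 ± 0.32), G6PC1 20.4-fold (-4.35 ± 0.18), PCK1 15.9-fold (-3.99 ± 0.35), CPS1 8.51-fold (-3.09 ± 0.08) and CYP2C8 7.06-fold (-2.82 ± 0.08), in 4 against 7 libraries. CYP1A2 (-3.77 ± 0.21), CYP1A1 (-3.08 ± 0.21) and CYP2B6 (-2.02 ± 0.17) fell too. SERPINB2 (3.66 ± 0.15), the serotonin receptor subunit HTR3A (3.57 ± 0.19) and the apolipoprotein APOA4 (3.55 ± 0.19) were the largest rises. Among the tubulins, TUBA1B (-1.54 ± 0.07), TUBB4B (-1.44 ± 0.06), TUBB2A (-1.36 ± 0.07) and TUBA4A (-1.09 ± 0.05) fell while TUBA1A rose (1.74 ± 0.14), all within a family of similar sequences. Of 5 genes picked by hand to follow over the doses, all of them lower at 0.1, TUBA1B alone was called at 0.03 (-1.23 ± 0.07). Most of the 70 genes changed at 0.03 moved the other way, as 53 rose and 17 fell. CYP7A1, at -0.64 ± 0.17, was lower there by less than a call needs.

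In Col, gluconeogenesis and glucocorticoid response fell in 4 of 9 members (median -0.82, adjusted p = 3.43e-05, and 0.00565 with an estimated correlation), and bile acid synthesis and transport in 7 of 13 (median -1.02, 4.96e-08 and 0.0323). Tubulins fell in 5 of 10 and rose in 1 (median -0.95, adjusted p = 9.61e-05), and CAR and PXR targets fell in 5 of 13 (0.000395), with adjusted p = 0.115 and 0.247 with an estimated correlation. Hepatocyte secreted proteins and enzymes fell in 3 of 18 members (median -0.54, adjusted p = 7.31e-09, and adjusted p = 0.116 with an estimated correlation). Endothelial markers moved with these groups, as 3 of 5 fell, TEK (-2.54 ± 0.37) and KDR (-1.64 ± 0.22) among them (adjusted p = 0.0214, and adjusted p = 0.108 with an estimated correlation), and 1 of 6 cholangiocyte and progenitor markers rose (median 0.59), without a call for that list. In cell division 0 of 21 members were called by edgeR (median 0.13, adjusted p = 0.126). Col changed 1138 genes, 348 of them upward, or 249 with limma on the variance-stabilised values, where TEK was not called (-0.74), and 70 at dose 0.03.

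Gri and Eth changed fewer genes in HepaRG. Gri at 100 lowered CRP 3.99-fold (-1.99 ± 0.12, 44.64 ± 7.53 against 178.1 ± 20.2 CPM), the hyaluronan-binding protein CEMIP (-1.78 ± 0.09), CYP4A11 (-1.57 ± 0.08), CYP1A1 (-1.34 ± 0.20) and the fatty acid binding protein FABP1 (-1.09 ± 0.07), and raised CYP3A43 (1.86 ± 0.28) and PHGDH (1.09 ± 0.08), the first enzyme of serine synthesis, in 4 against 7 libraries. CRP was called from 30 on (-1.36 ± 0.13), while at 10 it was at -0.63 ± 0.12, short of the size for a call. The integrated stress response was higher as a group (1 of 16 called, adjusted p = 0.000437, and 0.0142 with an estimated correlation) and tubulins were lower (0 of 10 called by edgeR, 1 adjusted over the list alone, median -0.36, 1.6e-05 and 0.0479). Of 5 endothelial markers 1 rose and 1 fell, without a call for the list. The mitochondrial share was 13.8 ± 0.727% against 12.5 ± 0.351% (exact permutation test, adjusted p = 0.03). Gri changed 259 genes, 63 of them upward, and 30 with limma on the variance-stabilised values, where CYP3A43 (0.98) and PHGDH (0.93) were not called.

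Eth at 300 raised SPOCD1 (2.48 ± 0.26), the small GTPase RASD1 (2.07 ± 0.15) and STC2 (1.92 ± 0.17), and lowered the cytokine TNFSF14 (-1.83 ± 0.08), the bile acid importer SLC10A1 (-1.53 ± 0.20) and the mitotic kinase PLK1 (-1.26 ± 0.10), in 4 against 7 libraries. Cell division fell in 6 of 21 members (median -0.88, adjusted p = 6.86e-14, and adjusted p = 0.0782 with an estimated correlation). The unfolded protein response of the endoplasmic reticulum was higher as a group (median 0.20, 2.77e-09 and 0.0417), with 0 of 14 members called by edgeR. Eth changed 214 genes, 110 of them upward, and 23 with limma on the variance-stabilised values, where STC2 (0.98) and SLC10A1 (-0.76) were not called. Mef at 30 changed 1 gene, C11orf86 (2.37-fold, 4.22 ± 1.17 against 1.77 ± 0.37 CPM, adjusted p = 0.00503), an open reading frame of uncharacterised function. The count was 0 in edgeR without treated replicate 1, 2 or 3, and 2 without DMSO replicate 5. It was 3 with a replicate block, which did not call C11orf86 (1.24), 4 with DESeq2 and 0 with limma on the variance-stabilised values. Ethio at 100 changed 0 genes in edgeR, with 974 at an unadjusted p under 0.05, and 6 with DESeq2 and 0 with limma on the variance-stabilised values. Of the lists, tubulins alone were called for Ethio, upward (median 0.08, adjusted p = 0.0334), but adjusted p = 0.333 with an estimated correlation, 0.162 or 0.554 without replicate 2 or 3, and 0.0539, 0.0604, 0.0732 or 0.0534 without DMSO replicate 1, 3, 4 or 6.

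Over all 424 pairs of list and comparison in HepaRG, 85 were called higher and 98 lower, and 40 of the 183 calls held with an estimated correlation. The integrated stress response was higher in 6 of 17 comparisons and lower in 0 by camera, and all 6 calls held. CAR and PXR targets were higher in 9 (6 held) and lower in 2, NRF2 targets higher in 8 (5 held) and lower in 2, and AhR targets higher in 5 (3 held) and lower in 3. Cholesterol synthesis and uptake was higher in 9 (2 held) and lower in 3 (1 held), and fatty acid synthesis higher in 3 (1 held) and lower in 4. Cell division was lower in 10 (2 held), gluconeogenesis and glucocorticoid response in 6 (3 held), acute phase proteins in 9 (1 held) and higher in 2, tubulins lower in 8 (1 held) and higher in 1, and bile acid synthesis and transport lower in 8 (2 held) and higher in 2. The unfolded protein response was lower in 9 (1 held) and higher in 2 (1 held), p53 targets lower in 3 (1 held) and higher in 3 (1 held), PPARA targets lower in 8 and higher in 2 (1 held), conjugation of thyroid hormone and steroids higher in 5 (1 held) and lower in 4, and heat shock proteins higher in 6 (1 held) and lower in 2.

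None of the calls of the remaining lists held with an estimated correlation. Metallothioneins were higher in 5 comparisons and lower in 1, hepatocyte proteins and enzymes lower in 7 and higher in 2, mitochondrially encoded proteins higher in 6 and lower in 4, and glycolysis and hypoxia response higher in 8 and lower in 3. Retinoic acid response was called with PHB alone (median 0.15, adjusted p = 0.0392, and adjusted p = 0.161 with an estimated correlation), and the call was lost without PHB replicate 2 (0.0649), 3 (0.069) or 4 (0.0976), or DMSO replicate 1 (0.0703) or 5 (0.0585). Endothelial markers were lower in 2 comparisons, and markers of cholangiocytes, stellate cells and macrophages were called in 0 by camera. HepaRG cultures hold bile duct-like cells beside hepatocyte-like ones, and the list of cholangiocyte and progenitor markers was at adjusted p = 0.323 with Myc.

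**Figure D2:**
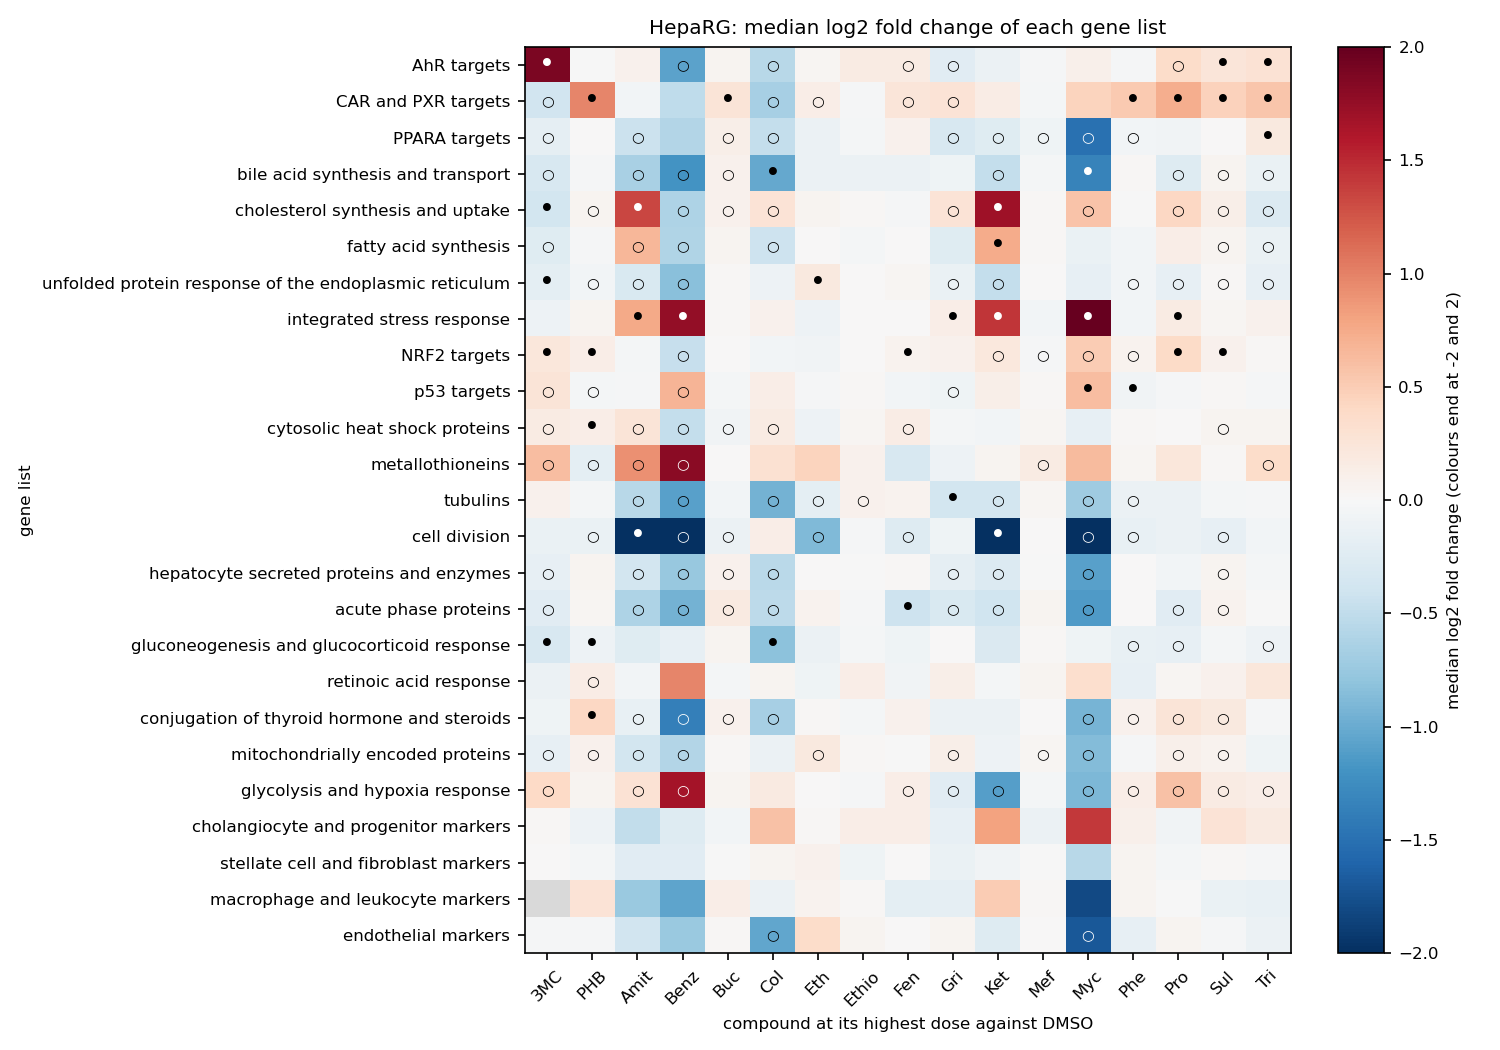
Median log2 fold change of each gene list (vertical) at the highest dose of each compound and with 3MC and PHB (horizontal) in HepaRG, as colour that ends at -2 and 2; filled dots mark calls that hold with an estimated correlation, open circles calls with the preset correlation alone, and grey a list with too few members. The integrated stress response carries 6 filled dots and CAR and PXR targets 6 among their higher calls.

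In HepaRG 8 of 15 compounds changed at least 20 genes at a dose below the highest and at every dose above it. The lowest active dose was 10 for Ket (237 genes), 31.6 for Amit (96) and Benz (65), 0.03 for Col (70), 100 for Myc (220) and Eth (29), and 30 for Gri (76) and Pro (56). Fen and Tri were active at the highest dose alone, and Buc, Ethio, Mef, Phe and Sul at none. PLCH2 rose below the lowest active dose of Ket, from dose 1 (2.82 ± 0.21), where 14 genes changed. TRIB3 rose from the lowest active dose with Amit, at 31.6 and 100 (1.12 ± 0.10 and 2.20 ± 0.09), and with Myc, at 100 and 300 (1.36 ± 0.08 and 4.41 ± 0.08). With Ket it also rose from the lowest active dose (1.46 ± 0.09 at 10). With Benz it did not, with 0.04 ± 0.10 at 31.6 and 3.09 ± 0.08 at 100. Eth was active at the highest dose alone without treated replicate 1, 2 or 3 or DMSO replicate 6 or 7, each of which left 7 compounds, and Fen at none without replicate 1. The number was 4 with limma on the variance-stabilised values, and 2 with a minimum of 100 genes.

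**Figure D3:**
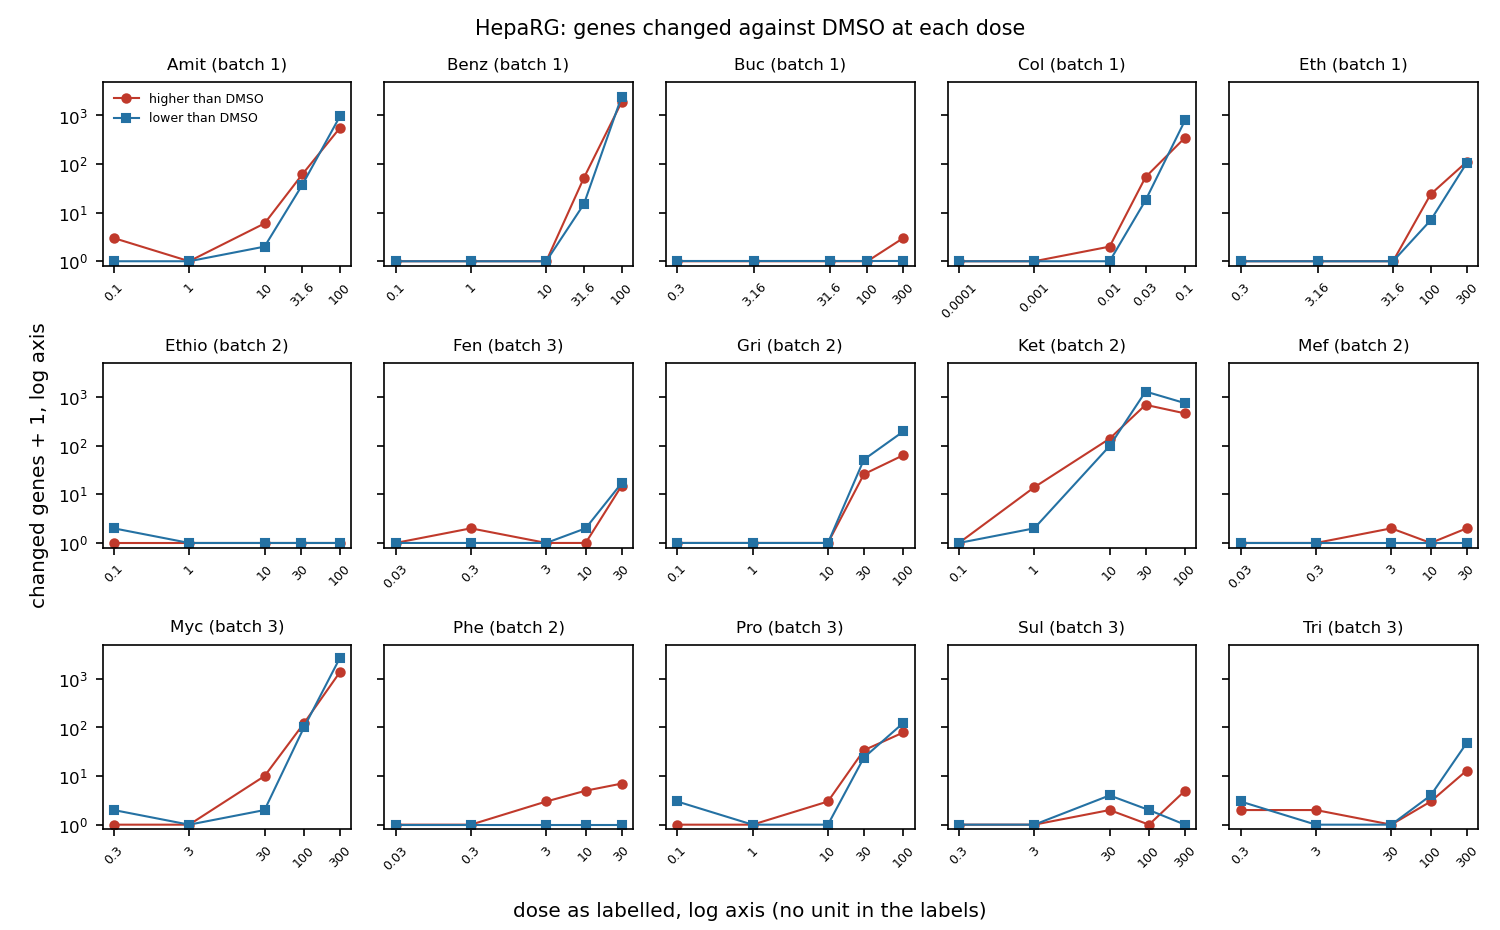
Number of changed genes plus 1 (log axis) against dose (log axis, no unit in the labels) for each of the 15 compounds in HepaRG, as red circles for genes higher and blue squares for genes lower than in DMSO. The counts for Ket peak at dose 30 (695 higher, 1306 lower) and are 463 and 753 at 100.

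In rat hepatocytes 4 of 15 compounds changed at least 20 genes at a dose below the highest and at every dose above it. Col changed genes at every dose, with 131 at 0.01, 501 at 0.1, 1192 at 1, 1028 at 10 and 1300 at 100, of which 302 rose and 998 fell. Benz changed 103 genes at 3.16 and 1196 at 31.6, Gri 274 at 10 and 409 at 100, and Pron 25 at 10 and 90 at 100. Pron was active at 100 alone without treated replicate 1 or 2 or DMSO replicate 6, which left 3 such compounds. At the highest dose alone, Eth changed 2190 genes (949 higher, 1241 lower), Ket 1208 (447 and 761), Ethio 597 (284 and 313), Myc 479 (234 and 245), Tri 122 (50 and 72), Phen 72 (22 and 50), Fenpicoxamid 55 (35 and 20), Sulf 44 (32 and 12) and Mef 42 (16 and 26). Each highest dose had 4 libraries against 7 DMSO libraries, except that Benz and Amit had 3.

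Amit at 10 changed 3 rat genes (1 without replicate 2 or 3, and 14 with DESeq2), while 21 rose at dose 1, which is not counted as active because the higher dose changed fewer than 20. Buc at 100 changed 0 genes in edgeR, with 600 at an unadjusted p under 0.05, and 0 with DESeq2 and with limma on the variance-stabilised values. Several of the smaller counts depended on 1 replicate number. Myc was at 1060 without replicate 2, 202 without replicate 3 and 315 without replicate 4. Fenpicoxamid was at 33 without replicate 1, 115 without replicate 2 and 16 without replicate 3 or 4, either of which left it without an active dose. Phen was at 35 and 43 without replicate 1 or 2, Mef at 26 and 21 without replicate 3 or 4, and Sulf at 21 and 27 without replicate 1 or 2 and at 28, 28 and 26 without DMSO replicate 1, 3 or 5. With limma on the variance-stabilised values every nonzero rat count of a highest dose was over 1.5 times lower, for instance 820 for Eth and 486 for Col.

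**Figure D4:**
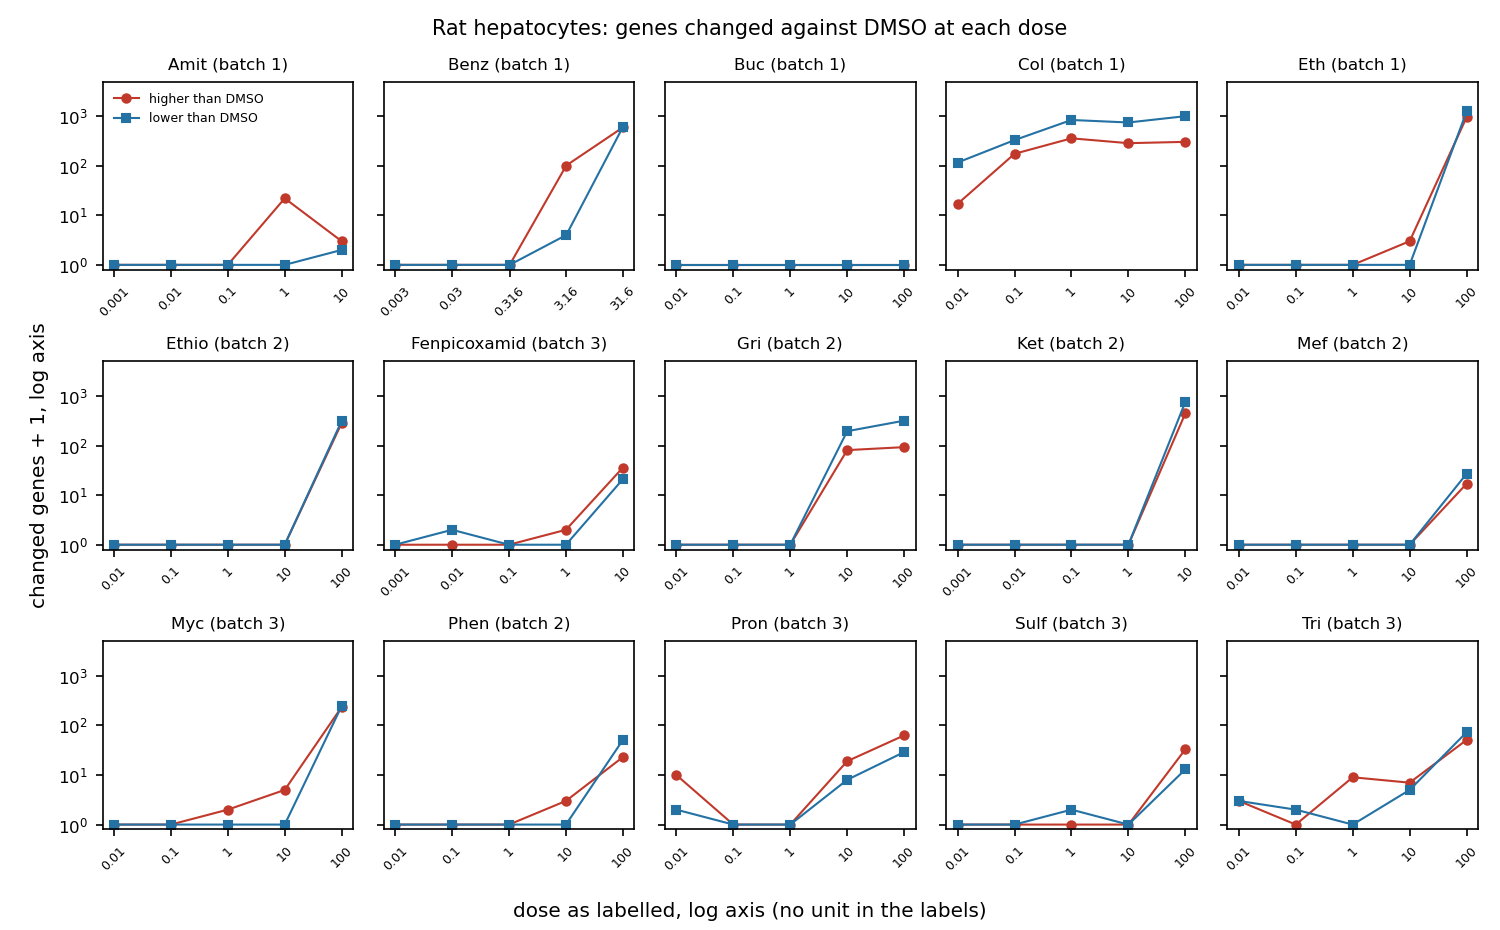
Number of changed genes plus 1 (log axis) against dose (log axis, no unit in the labels) for each of the 15 compounds in rat hepatocytes, as red circles for genes higher and blue squares for genes lower than in DMSO. Col has changed genes at all 5 doses, from 16 higher and 115 lower at 0.01 to 302 and 998 at 100.

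3MC changed 273 rat genes, 93 upward and 180 downward, in 12 treated against 21 DMSO libraries, and 258, 257 and 389 in the batches alone. The gene with the ID ENSRNOG00000040287 was at 161.0 ± 42.1 CPM against 0.01 ± 0.03 in DMSO, and ENSRNOG00000002331 rose 371-fold (8.54 ± 0.20, 93.4 ± 31.0 against 0.24 ± 0.18 CPM, adjusted p = 8.73e-28). The largest falls were smaller, with ENSRNOG00000032703 at -1.67 ± 0.11 and ENSRNOG00000001198 at -1.60 ± 0.13. The count was 74 with limma on the variance-stabilised values and 646 without the low-count filter. PHB raised 6 rat genes and lowered 0 by edgeR, DESeq2 called 7 and limma on the variance-stabilised values 5. The batches alone gave 4, 3 and 46. BLANK, which the labels do not explain, differed from DMSO in 71 genes (39 higher, 32 lower) in 3 against 21 libraries. That count was 10 without the BLANK library of batch 1, 16 without that of batch 2 and 143 without that of batch 3. It was 45 without DMSO replicate 4 of every batch, and 10 with limma on the variance-stabilised values.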

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

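The tests on thinned libraries, on libraries left out of rat PHB batch 3 and of treatment by batch were chosen only after the counts of changed genes had been seen.

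In HepaRG, Ket changed fewer genes at 100 (1216) than at 30 (2001), although INSIG1 was about as high at 100 (2.91) as at 30 (2.85). TRIB3 (2.88 against 3.49) and MKI67 (-2.53 against -3.56) moved less at 100. Lower depth at 100 is argued against, since with all libraries thinned to 10466528 counts the ratio of the counts at 100 and 30 was 0.63 (1178 and 1869 genes). So is a single library at 30 that stood apart. With each replicate number left out at every dose, the ratio of the count at 30 to that at 100 was at least 1.5. Exchanged labels are argued against too, since 54.4% of the genes called at 10 changed more at 100. No biological explanation was tested.

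BLANK differed from rat DMSO in 71 genes. Whether a single BLANK library that stood apart explains this count is not settled. The count fell to 10 without the library of batch 1, but also to 16 without that of batch 2. Part of either fall may be lost power, as 2 libraries leave less than 3. Without the library of batch 3 the count rose to 143, so that library lowered it. Depth is argued against, since 59 genes were called after thinning to 8904560 counts. No biological explanation was tested, as the labels do not say what BLANK is.

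PHB changed 46 rat genes in batch 3 but 4 and 3 in batches 1 and 2. Greater depth in batch 3 is argued against by 39 genes after thinning to 7566228 counts. A single PHB library that stood apart is argued against by a lowest count of 30 (without PHB replicate 3), and the lowest without a DMSO library was 28 (DMSO replicate 3). Within batch 3, 1 of 25 splits gave as many genes, the real one, with 1 as the highest other, which bears on PHB against DMSO in that batch and not on the difference between batches. A test of that difference, of treatment by batch, passed for 1 of 11947 genes, so a chance difference between the counts stays open.

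The response to 3MC differed between the batches in rat for 4 of 11902 genes and that to PHB for 1 of 11947, by a term for treatment by batch (1403 and 639 at an unadjusted p under 0.05), and in HepaRG for 0 genes each in edgeR, with 905 and 674 at an unadjusted p under 0.05.

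A Dixon test, which flags about 1 in 20 tests by chance, was run on groups of at least 4 libraries. It was run 22 times in rat, on total gene counts. In HepaRG it was run 60 times, on totals and on CYP1A1, CYP1A2, CYP2B6 and CYP3A4 in DMSO, 3MC and PHB. Smaller groups were not tested, such as HepaRG Eth 100, with totals from 21743151 to 102060676. In some of the tests single libraries lay apart from the others of their group. By total gene count these were rat Eth 100 replicate 3 (10198484, others 12552776 to 12810182), rat PHB batch 1 replicate 4 (15438673, others 13421416 to 13695320), rat DMSO batch 1 replicate 4 (9908938, others 11398700 to 12463581), HepaRG Col 0.1 replicate 2 (19544850, others 13911858 to 14306005), HepaRG Mef 30 replicate 4 (11368877, others 14700468 to 15108906) and HepaRG Gri 100 replicate 4 (22448735, others 13496616 to 14798470). By level in HepaRG DMSO, CYP1A2 was at 4.93 CPM in batch 1 replicate 7 (others 7.47 to 8.85) and CYP2B6 at 112.1 CPM in batch 2 replicate 3 (others 161.2 to 186.8). These CPM are on total gene counts without TMM factors.

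For all counts of changed genes but 3, 1 of 25 splits of the same libraries, the real one, gave as many genes. That is the lowest share 25 splits can give and is not corrected for the number of comparisons. It argues against chance for a single comparison but does not exclude it. For rat Amit, rat Myc, rat Fenpicoxamid and HepaRG Buc the lowest count with 1 replicate number left out was 1, 202, 16 and 0 genes. These counts were no higher than the highest other split, so the splits are not taken to argue against chance for these compounds. The highest other split does not measure chance alone, since a split can keep most treated libraries together. It kept 3 of the 4 for rat Myc (471), rat Fenpicoxamid (36) and HepaRG Benz (911). For HepaRG Myc (2586) it kept 0, so the treated libraries made up most of the group taken as DMSO. In rat the highest of the other splits was 68 for Benz (1196), 0 for Col (1300), 300 for Eth (2190), 1 for Amit (3), 87 for Gri (409), 0 for Phen (72), 0 for Ket (1208), 14 for Mef (42), 310 for Ethio (597), 3 for Sulf (44), 36 for Fenpicoxamid (55), 9 for Pron (90), 471 for Myc (479), 29 for Tri (122), 57 for 3MC (273), 0 for PHB (6) and 0 for BLANK (71). In HepaRG it was 911 for Benz (4304), 1 for Buc (2), 148 for Amit (1512), 5 for Eth (214), 1 for Col (1138), 127 for Ket (1216), 57 for Gri (259), 0 for Phe (6), 0 for Fen (30), 0 for Sul (4), 20 for Tri (59), 2 for Pro (201), 2586 for Myc (4081), 1 for 3MC (171) and 1 for PHB (31). For HepaRG Mef the splits do not argue against chance (1 gene, 2 of 25, highest other 1). For rat Buc and HepaRG Ethio the real count was 0 in edgeR (600 and 974 at an unadjusted p under 0.05), so all 25 of 25 splits reach it by construction and the splits say nothing about chance. The highest other split was 1 for Ethio and 90 for rat Buc, the latter in 1 split while the rest gave 0 or 1, and what set those libraries apart was not tested.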

How the results depend on the processing

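Estimated correlations for lists and the settings below were chosen in advance, and the cause of a moved value was not tested. Rat lists and the comparison of rat with HepaRG were not run, for want of rat symbols. Of 420 results for named genes 327 held in every setting, and of 183 list calls 40. The number of active doses held for 15 of 30 series of a compound in a cell type, which include series without an active dose. It counted as held within a factor of 1.5, so 2 active doses in place of 3 counted as held.

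With limma on the variance-stabilised values, whose scale is compressed at low counts, the counts were, in rat, Benz 419, Col 486, Eth 820, Amit 1, Gri 79, Phen 15, Ket 467, Mef 7, Ethio 103, Sulf 8, Fenpicoxamid 5, Pron 26, Myc 109, Tri 25, 3MC 74 and BLANK 10. In HepaRG they were Benz 1540, Buc 1, Amit 421, Eth 23, Col 249, Ket 349, Gri 30, Mef 0, Fen 6, Sul 2, Tri 8, Pro 40, Myc 1422, 3MC 22 and PHB 8, with 4 compounds active below their highest dose. With the DESeq2 Wald test they were rat Amit 14 and HepaRG Buc 1, Ethio 6, Mef 4 and Sul 9. With a replicate block they were rat Amit 1, Phen 46 and Mef 22, and HepaRG Buc 0, Mef 3, Fen 7, Tri 30 and Pro 104. Without a low-count filter 3MC gave 646 in rat and 749 in HepaRG, and PHB 68 in HepaRG. In batches alone PHB gave 3 (batch 2) and 46 (batch 3) in rat, and 20, 18 and 19 in HepaRG. With a minimum of 100 genes, 2 HepaRG compounds were active below the highest dose. Of the list calls, 40 held with an estimated correlation. Reversed were glycolysis and hypoxia response in Tri with a replicate block (adjusted p = 0.726) and CYP1A1 with PHB in batch 2 alone (-0.03).

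With 1 replicate number or 1 BLANK library left out, counts in rat ran from 1 to 3 for Amit, 35 to 77 for Phen and 21 to 50 for Mef. They ran from 21 to 48 for Sulf, 16 to 115 for Fenpicoxamid, 202 to 1060 for Myc and 10 to 143 for BLANK. In HepaRG they ran from 0 to 3 for Buc, 0 to 2 for Mef, 18 to 32 for Fen and 34 to 54 for Tri. A treated number was left out at all doses of its compound, so such shifts cannot be assigned to single libraries at the highest dose. The replicates are named beside each result in the report.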

Other observations

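The shared-gene tests in the next paragraph and the sets of genes taken from 3MC and PHB were chosen only after the results were seen.

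The sets hold the genes that 3MC or PHB raised or lowered in the other 2 batches, so that no set shares libraries with the compound it was tested on. In HepaRG the genes PHB raised were higher with Pro (median log2 fold change 1.08, 12 of 22 rose, adjusted p = 0.000232 with an estimated correlation), Sul (0.52, 1.39e-05), Tri (0.50, 0.00491), Phe (0.47, 1.39e-05) and Buc (0.33, 8.86e-05), and lower with Col (-1.26, 12 of 20 fell, 0.0243). The genes 3MC lowered were lower with Col (-1.20, 48 of 97, 0.000173), Benz (-1.11, 51 of 97, 0.0166), Myc (-1.63, 60 of 100, 0.0498) and Amit (-0.66, 0.0255), and those it raised were higher with Eth (0.39, 8 of 87, 0.00802). In rat the genes PHB raised were higher with Phen (1.26, 5 of 7 rose, 0.0448) and Amit (1.14, 0.0133), the genes 3MC raised were higher with Pron (0.25, 0.00541), and the genes it lowered were lower with Col (-1.47, 128 of 205 fell, 0.0029). For Tri the median of the genes 3MC raised was 0 in rat and 0.15 in HepaRG, where CYP1A1 and CYP1A2 rose. The bound of 0.2 set for the rat median was thus too high to tell the cell types apart, and an action of Tri on single genes in rat stays open.

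In HepaRG, Amit and Ket, fitted with DMSO of different batches, changed 680 genes in the same direction against 48.8 for independent lists (13.93 times as many), Amit and Myc 972 against 167.4 (5.81 times) and Ket and Myc 869 against 137.1 (6.34 times). The excess alone does not set these pairs apart, since every HepaRG pair of compounds compared across batches exceeded independent lists, from 2.77 times for Benz and Gri to 52.85 times for Eth and Fen (8 genes against 0.2). Few genes moved in opposite directions (6 against 41.9 for Amit and Ket, 30 against 135.3 for Amit and Myc, 12 against 115.6 for Ket and Myc), and with Benz and Myc (Spearman 0.641) these pairs had the highest correlations (0.588, 0.489 and 0.577). TRIB3 rose and MKI67 fell with Amit, Ket and Myc, but also with Benz, and no explanation for the shared genes was tested further. That cholesterol synthesis rose in 19 of 25 members with Amit, 22 with Ket and 5 with Myc was not tested for a difference.

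The share of counts from the spike-in controls did not pass between any highest dose and DMSO (exact permutation test, lowest adjusted p = 0.82). Markers of cholangiocytes, stellate cells and macrophages had medians from -0.50 to 1.42, -0.55 to 0.08 and -1.80 to 0.50 over the comparisons, with 0 list calls by camera. In Benz 3 of 6 retinoic acid response genes rose without a call for the list (median 0.97, adjusted p = 0.128).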
